A study of Homo sapiens with 128 samples.

How the data were processed

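The series compared 4 commercial library preparation kits for chromatin immunoprecipitation followed by sequencing (ChIP-seq) in LNCaP, an established line of human prostate adenocarcinoma cells that respond to androgen. The kits were NEXTflex from Bioo Scientific (called Bioo here), MicroPlex version 2 from Diagenode (Diagenode), HyperPrep from Roche (KAPA) and NEBNext Ultra II from New England BioLabs (NEB). Of the 128 libraries in the labels, 108 had a deposited list of enriched regions and were analysed: 48 for H3K4me3, 48 for H3K27me3 and 12 for CTCF. The other 20 libraries, 12 of input chromatin and 8 of total histone H3, had no list and were not used here. Each histone mark had 6 amounts of input DNA (100 pg, 250 pg, 500 pg, 1 ng, 5 ng and 10 ng) in 2 Sets per kit, and CTCF had 3 Sets per kit with no amount given. Kit, target, amount and Set were taken from the labels. The labels did not state what a Set was, so p-values measure the spread between these libraries, which may be technical.

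One list was deposited per library, so peaks had been called library by library. The submitters' processing notes name Bowtie 1.1.2, MACS 1.4.2 and the build hg19, without stating their roles. In the H3K4me3 and CTCF lists the authors deposited a position, a tag count per peak, a fold enrichment (a ratio) and a score equal to -10 times the log10 of the peak's p-value, per the file headers and the range of the values. That score was never below 50 in these lists. In the H3K27me3 lists the authors deposited domains on a grid of 20 kb bins, each with a count of bins, a summed z-score, a p-value and a false discovery rate, per the file headers. All 204976 domains had a width equal to their count of bins times 20 kb, and every false discovery rate was under 0.05. The caller of these domains is not given in the sources used here. Scores and folds were the authors' own values of each peak and were used only to filter or rank peaks within a list, and the tag counts entered no comparison. No 2 of the 108 lists were identical.

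The name of each deposited list carries a read number in M (as in Mb). What this number counts was not stated, so it is called the stated read number and is the only measure of depth used. It was equal across kits within each CTCF Set (4.5 M in Set 1, 1 M in Set 2 and 2.5 M in Set 3), and ran from 0.8 to 35 M for H3K4me3 and from 1.5 to 53 M for H3K27me3. Fewer than 5 M reads were stated for 4 H3K4me3 and 4 H3K27me3 libraries, and the results were also computed without these, an alternative chosen after seeing the data.

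From the positions, the number of peaks or domains, their median width and the length covered were computed per list. Lists were merged per target wherever regions touched, and a region counted as called in a library when at least 1 bp of it overlapped a peak. The reference regions of a histone mark were merged regions with a peak in both Sets at 10 ng in at least 3 of the 4 kits. For CTCF they needed a peak in at least 2 Sets in at least 3 kits. The reference held 14188 regions for H3K4me3, 2318 for H3K27me3 and 4391 for CTCF. Overlap between lists was the Jaccard index in base pairs, given in percent.

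Kits were compared by a 2-sided permutation test of the kit labels within each input amount, with 100000 resamples, or complete enumeration for CTCF. Pairs of kits were compared by exact permutation within input, with Benjamini-Hochberg adjustment over the 6 pairs. List lengths, covered lengths and widths were tested as log2 values. Trends with input were least-squares slopes of log2 list length per doubling of input DNA, tested by permuting the input labels and adjusted over the 8 trends. The effects of a kit pair in both marks were compared by an exact sign-flip test over the 6 inputs. The tests of the comparisons other than the single trends, kit pairs and regions formed a family of 20, adjusted together, which included the sign-flip test of the largest difference between marks. For single regions, the number of libraries with a call in one kit was tested against the other kits by an exact test conditional on the number of calls at each input, over regions called in at least 2 and at most all but 2 libraries, with Benjamini-Hochberg adjustment over regions and kits and a threshold of 0.05. The regions named are, per kit and direction, the 3 with the smallest adjusted p among those past the threshold, ties going to the larger difference in share of libraries. Tests, samples, this rule and most alternatives were fixed before the data were examined.

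The tests were checked on simulated data. With 200 regions changed strongly by construction in one kit, the region test recovered 98.5% of them in the H3K4me3 layout and 99.5% in the H3K27me3 layout, and 0% in the CTCF layout, where 3 libraries per kit are too few for any region to pass. With no kit effect, the list length test called 2% of simulated sets of 48 libraries at the 0.05 threshold, and with one kit shifted by 1 SD it called 65.5%. The simulated libraries were independent, with equal spread and, apart from the changes made, equal calling rates in every kit. The real lists differ between kits in spread and stated read number, so these rates may not hold for them.

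The alternatives were a stricter threshold (p of 1e-10 or less), the same number of top-ranked peaks in each list, other overlap rules and references, leaving out the 100 pg libraries or each Set, adjusting for the stated read number, and the Set number as a block. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Coordinates are on hg19 as deposited, with H3K27me3 starts moved by 1 so that they count from 1. The base of the starts in the other lists is not given in the sources used here, and these are printed as deposited. No hg19 sequence or annotation was used here, so the planned tests of promoters of fixed gene lists and of the GC content of peaks were not run, and regions are named by position alone.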

Results

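Lists of enriched regions were compared for 3 chromatin targets in LNCaP cells: trimethylated lysine 4 of histone H3 (H3K4me3), which marks active promoters, trimethylated lysine 27 (H3K27me3), which marks broad domains silenced by Polycomb, and CTCF, a protein that binds DNA at short motifs. Each histone mark had 12 libraries per kit, 2 at each of 6 amounts of input DNA, and CTCF had 3 per kit. H3K4me3 lists held 11531 to 17621 peaks and covered 9.91 to 37.0 Mb. H3K27me3 lists held 438 to 5226 domains and covered 14.7 to 1085 Mb. CTCF lists held 2782 to 18316 peaks over 1.27 to 7.37 Mb. The stated read number differed between kits. For H3K4me3 its geometric mean was 8.01 M in Bioo, 18.8 M in KAPA, 21.3 M in Diagenode and 22.3 M in NEB, a 2.78-fold range (permutation p = 8e-05, n = 12 per kit). For H3K27me3 it was 13.7 M in Bioo, 18.3 M in KAPA, 26 M in Diagenode and 31.4 M in NEB, a 2.30-fold range (permutation p = 1e-05, the smallest that the resamples can give). This comparison of read numbers was added after the files were seen.

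The first question was whether the kits gave different numbers of H3K4me3 peaks from the same amount of DNA. Over all inputs the geometric mean was 14699 peaks in Bioo, 15059 in KAPA, 15456 in Diagenode and 15856 in NEB, with SDs on the log2 scale of 0.17, 0.10, 0.05 and 0.12 (n = 12 each). The gap opened at the lowest input. At 100 pg, Bioo lists held 12088 ± 788 peaks and NEB lists 16063 ± 939, whereas at 10 ng they held 16195 ± 936 and 15885 ± 1918 (mean ± SD, n = 2). The NEB to Bioo ratio over all inputs was 1.08, which did not pass the permutation test (p = 0.0645, adjusted p = 0.143). Among peaks with a p of 1e-10 or less the ratio was 1.21 (permutation p = 0.0004), and over inputs of 1, 5 and 10 ng it was 0.998 (permutation p = 0.770). The test of the 4 kits passed within each Set alone (permutation p = 0.000820 in Set 1 and 0.0347 in Set 2), with NEB highest and KAPA lowest in Set 1, and Diagenode highest and Bioo lowest in Set 2. It also passed after adjustment for the stated read number (permutation p = 0.0189), with Bioo highest and KAPA lowest and a NEB to Bioo ratio of 0.989.

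H3K4me3 peaks were narrower in Bioo lists at low input. At 100 pg the median width was 884 ± 101 bp in Bioo and 1960 ± 10.6 bp in NEB, while at 10 ng Bioo peaks were the widest, at 2078 ± 36.1 bp against 2018 ± 104 bp in NEB (n = 2). Over all inputs it averaged 1648 ± 467 bp in Bioo and 1998 ± 87.9 bp in NEB (SD, n = 12), and NEB was 1.27-fold wider at matched input (permutation p = 0.00024, adjusted p = 0.00173). The covered length averaged 25.6 ± 8.98 Mb in Bioo, 28.8 ± 5.24 Mb in KAPA, 30.3 ± 2.72 Mb in Diagenode and 32.3 ± 3.67 Mb in NEB, a 1.35-fold NEB to Bioo ratio at matched input (permutation p = 0.00185, adjusted p = 0.0074). At 100 pg, Bioo lists covered 11.4 ± 2.04 Mb and NEB lists 31.8 ± 1.72 Mb (n = 2). Without the libraries under 5 M reads the covered-length ratio was 1.12 and did not pass (permutation p = 0.114).

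For H3K27me3 the test of list length passed over all inputs. The geometric mean was 3320 domains in Bioo, 3827 in KAPA, 4531 in Diagenode and 4748 in NEB, with SDs on the log2 scale of 0.93, 0.60, 0.17 and 0.11 (n = 12 each). The NEB to Bioo ratio was 1.43 (permutation p = 0.0113, adjusted p = 0.0329). Bioo lists were shorter than the NEB list of the same input and Set number in every one of the 12 comparisons (adjusted p = 0.0015, exact permutation), and shorter than the Diagenode list in every one of the 12 (adjusted p = 0.0005, exact permutation). KAPA lists were also shorter than NEB lists, at a ratio of 0.806 (adjusted p = 0.012, exact permutation). At 100 pg the lists held 1886 ± 2048 domains in Bioo, 2012 ± 1278 in KAPA, 3594 ± 74.2 in Diagenode and 4686 ± 255 in NEB (n = 2), where single lists ran from 438 in Bioo Set 1 to 4866 in NEB Set 2. Adjusted for the stated read number, at a slope of 0.52 within input, the NEB to Bioo ratio was 0.925 and the test of the 4 kits did not pass (permutation p = 0.879). Read number itself differed between kits, so this adjustment also removes any kit effect that goes with it. The test passed without the libraries under 5 M reads, at a ratio of 1.19 (permutation p = 0.00014), and at 1, 5 and 10 ng, at 1.11 with Diagenode the highest kit (permutation p = 0.0303).

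For H3K27me3, covered length and domain width did not pass over all libraries. The NEB to Bioo ratio of covered length was 1.68 (permutation p = 0.156, adjusted p = 0.283), and the largest ratio of median widths was 1.06 (permutation p = 0.990). Without the libraries under 5 M reads the test of covered length passed (permutation p = 0.0116), with NEB highest and Diagenode lowest, and a NEB to Bioo ratio of 1.08.

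**Figure D1:**
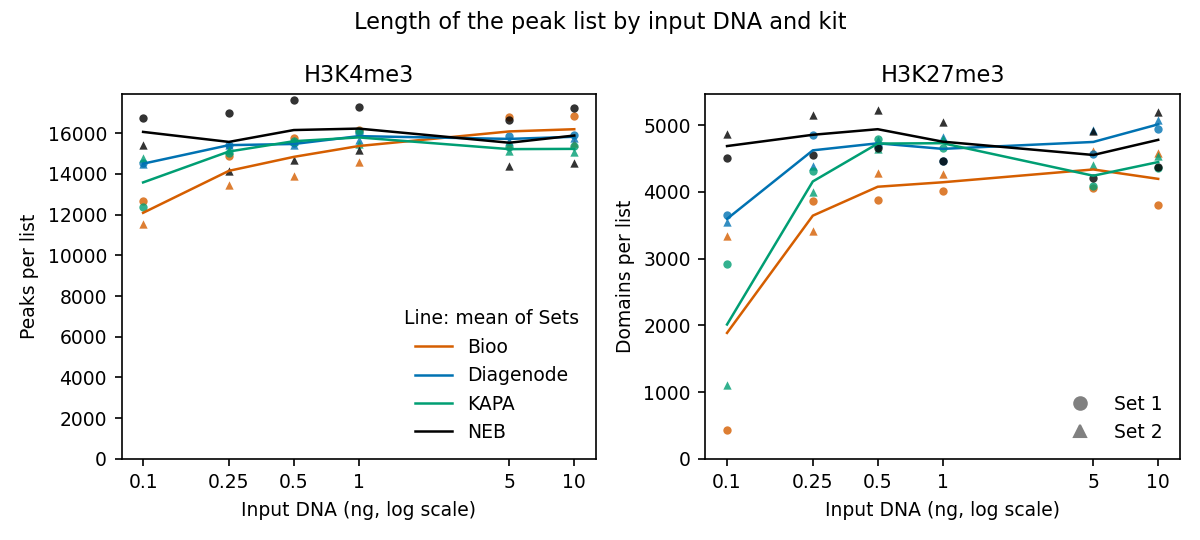
Number of peaks (H3K4me3) or domains (H3K27me3) per deposited list against the amount of input DNA in ng on a log scale, with 1 point per library, circles for Set 1, triangles for Set 2, and lines through the mean of both Sets for each kit. At 0.1 ng the mean of both Sets is lowest in Bioo for both marks, and the NEB means change little over the range.

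The input series asked how far the DNA can be reduced before peaks are lost. Bioo and Diagenode lists grew in number with input, KAPA lists grew in covered length, and neither trend passed in NEB lists. Stated reads rose with input too, for H3K4me3 from a mean of 0.85 M at 100 pg to 31.5 M at 10 ng in Bioo. The same means were 9.5 and 32 M in Diagenode, 7 and 27.5 M in KAPA and 21 and 25 M in NEB. For H3K27me3 they were 2.25 and 26.5 M in Bioo and 24.5 and 35 M in NEB. The slopes were not adjusted for read number, so input and read number cannot be told apart. For H3K4me3 the log2 slope per doubling of input was 0.06 in Bioo and 0.01 in Diagenode (permutation, adjusted p = 0.00524 for both), 0.02 in KAPA (adjusted p = 0.216, permutation) and -0.0032 in NEB (adjusted p = 0.838, permutation). For H3K27me3 it was 0.19 in Bioo (adjusted p = 0.030, permutation), 0.05 in Diagenode (adjusted p = 0.00992, permutation), 0.13 in KAPA (adjusted p = 0.069, permutation) and -0.0057 in NEB (adjusted p = 0.782, permutation), with n = 12 libraries per slope. Slopes of covered length, added after the data were seen, passed in KAPA as well, at 0.08 for H3K4me3 and 0.32 for H3K27me3 (permutation, adjusted p = 0.0154 for both), and did not pass in NEB (permutation, adjusted p = 0.819 and 0.0698). At the stricter threshold the Bioo slope was 0.14 for H3K4me3 and 0.47 for H3K27me3. Without the 100 pg libraries the H3K4me3 slope was 0.036 in Bioo and 0.0064 in Diagenode (permutation p = 0.0307 and 0.0418). The H3K27me3 trends rested on the lowest input. Without it the slope was 0.033 in Bioo (permutation p = 0.117), 0.017 in Diagenode (permutation p = 0.114) and -0.0028 in KAPA (permutation p = 0.856), and without Set 2 the slope was 0.31 in Bioo and 0.038 in Diagenode (permutation p = 0.241 and 0.190). The difference in slope between kits did not pass an exact permutation test of the 8 slopes of either mark (p = 0.0762 for H3K4me3 and 0.190 for H3K27me3). Without the 100 pg libraries that test passed for H3K4me3 (exact permutation p = 0.0381, slope difference 0.037).

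The kits also differed in the recovery of shared regions, which was not adjusted for the stated read number. Of the 14188 H3K4me3 reference regions, Bioo libraries overlapped 90.5 ± 10.4%, KAPA 97.2 ± 6.08%, NEB 98.6 ± 1.2% and Diagenode 98.9 ± 1.29% (SD, n = 12). At 100 pg the values were 74.2% and 68.8% in the Bioo Sets, with 0.9 and 0.8 M stated reads. They were 98.8% and 99% in the NEB Sets, with 19 and 23 M. The Diagenode Sets had 96.5% and 96%, with 10 and 9 M. KAPA at 100 pg had 78.1% in Set 1, with 2 M stated reads, and 96.7% in Set 2, with 12 M. The kits differed by 8.41 percentage points between Diagenode and Bioo (permutation p = 1e-05, the smallest that the resamples can give, adjusted p = 0.0002). That difference was 3.41 percentage points without the libraries under 5 M reads (permutation p = 4e-05), 5.35 with the same number of top-ranked peaks, 14 at the stricter threshold and 23.7 where a peak had to cover 50% of a region (permutation p = 1e-05 for these 3). With each kit's reference taken from the other 3 kits it was 7.92 (permutation p = 1e-05). Bioo was below Diagenode in each of the 12 comparisons at the same input and Set number, below KAPA in each of the 12, and below NEB in all but 2.

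Of the 2318 H3K27me3 reference domains, Bioo libraries overlapped 82.8 ± 25.1%, KAPA 86.8 ± 22%, Diagenode 94.2 ± 4.97% and NEB 97.8 ± 1.54% (SD, n = 12). The lowest values were 11.7% in Bioo Set 1 and 25.7% in KAPA Set 2, both at 100 pg, where NEB libraries reached 95% and 96.7%. Stated reads were 1.5 M in that Bioo library, 2 M in that KAPA library, and 26 and 23 M in the NEB libraries. Recovery was not adjusted for them. NEB exceeded Bioo by 15 percentage points (permutation p = 0.00026, adjusted p = 0.00173) and exceeded both Bioo and KAPA in each of the 12 comparisons at the same input and Set number (adjusted p = 0.000514 for both, exact permutation). That difference was 6.23 percentage points without the libraries under 5 M reads (permutation p = 1e-05) and 3.52 with the same number of top-ranked peaks (permutation p = 0.00024). Without Set 1 it was 11.8, KAPA was the lowest kit, and the test of the 4 kits did not pass (permutation p = 0.0608).

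**Figure D2:**
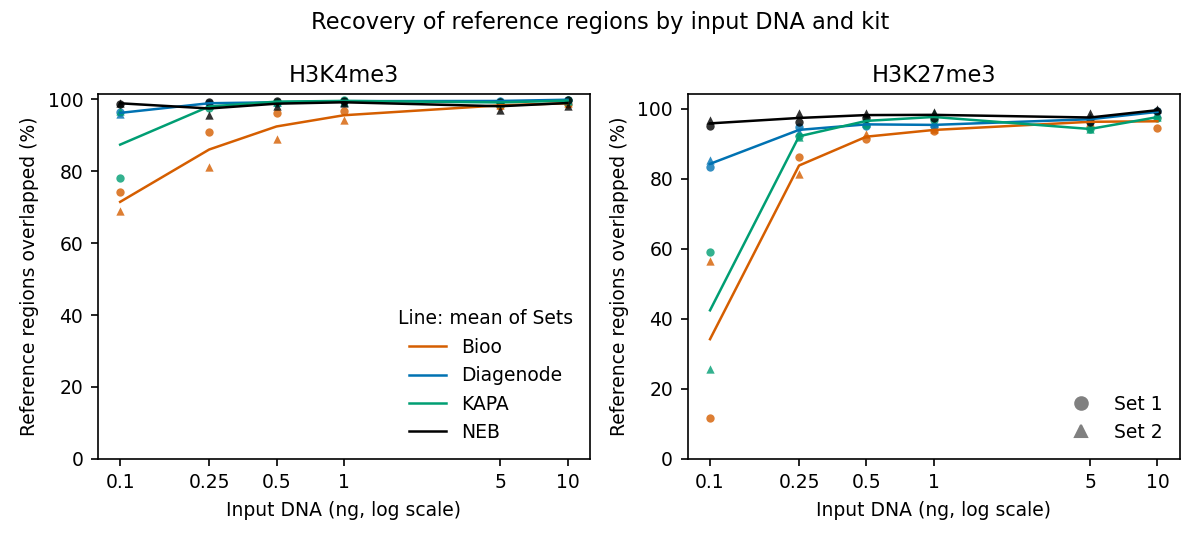
Percent of reference regions overlapped by each library against the amount of input DNA in ng on a log scale, with 1 point per library, circles for Set 1, triangles for Set 2, and lines through the mean of both Sets for each kit. At 0.1 ng, Bioo libraries reach 74.2% and 68.8% for H3K4me3, and all libraries of 5 and 10 ng lie above 94% for both marks. The reference regions were defined from the 10 ng libraries, so high recovery at 10 ng follows in part from that definition.

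The next comparison asked how well a kit's Sets reproduced each other. For H3K4me3 the overlap of the Set 1 and Set 2 lists was highest in Diagenode, at 87.8 ± 1.22%, followed by KAPA at 81.7 ± 15.6%, NEB at 77.4 ± 3.04% and Bioo at 69.0 ± 11.1% (SD over 6 inputs). The Diagenode to Bioo difference was 18.8 percentage points (permutation p = 0.0115, adjusted p = 0.0329), and 8.47 as a share of peaks. The order changed at 1, 5 and 10 ng, where KAPA was highest at 88.8%, Diagenode had 88.5%, Bioo 78.4% and NEB was lowest at 77.6% (exact permutation p = 0.0243). For H3K27me3 it was 58.8 ± 0.863% in NEB, 56.5 ± 1.74% in Diagenode, 51.3 ± 21.9% in KAPA and 47.7 ± 20.6% in Bioo, and the test did not pass (permutation p = 0.362). At inputs of 1, 5 and 10 ng it passed (exact permutation p = 0.00347), with KAPA highest at 60.5%, then NEB at 59.2%, Bioo at 57.3% and Diagenode at 56.1%. At 100 pg the H3K27me3 overlap was 5.9% in Bioo and 6.5% in KAPA, against 57.5% in NEB. There Set 1 and Set 2 covered 14.7 and 216 Mb in Bioo, and 409 and 30.2 Mb in KAPA. Such unequal lengths alone keep the Jaccard index low, even where the shorter list lies within the longer one. As a share of peaks the 100 pg values were 48.2% in Bioo, 53.6% in KAPA and 78.6% in NEB. Stated reads were 1.5 and 3 M in these Bioo libraries and 4 and 2 M in those of KAPA. Measured as the share of peaks overlapped, the test for H3K27me3 also passed (permutation p = 0.00605), with NEB at 79.3%, Diagenode at 78.7%, Bioo at 73.2% and KAPA at 73.0%.

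In the planned test, lists of different Sets were more alike when the kit was the same for H3K4me3 only. Stated reads for H3K4me3 at 100 pg were 0.9 and 0.8 M in the Bioo Sets and 10 and 9 M in Diagenode. They were 19 and 23 M in NEB and 2 and 12 M in KAPA. The overlaps were not adjusted for read number, so a shared kit cannot be told apart from a similar read number. For H3K4me3 the mean overlap was 79.0% between Sets of the same kit and 75.5% between Sets of different kits, higher for the same kit at 6 of 6 inputs (difference 3.45 percentage points, 1-sided permutation p = 0.00155, adjusted p = 0.0074), and by 1.05 percentage points as a share of peaks (permutation p = 0.00016). For H3K27me3 the values were 53.6% and 52.0% (1-sided permutation p = 0.201), and the difference passed only when measured as the share of peaks (1.42 percentage points, permutation p = 0.0003). For CTCF they were 16.1% and 15.8% (1-sided exact permutation p = 0.170), and with the same number of top-ranked peaks in each list the difference was 0.86 percentage points and passed (exact permutation p = 0.00174). Within one Set and input, lists of different kits overlapped by 76.3 ± 14.8% for H3K4me3, 69.2 ± 22.8% for H3K27me3 and 24.1 ± 13.4% for CTCF (SD over pairs of lists). For H3K27me3 and CTCF this was above the overlap between Sets of the same kit, 53.6% and 16.1%. For H3K4me3 it was below it, 79.0%. A shared Set was not tested against a shared kit.

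CTCF lists were longer in Set 3 than in the other Sets in every kit, and the spread between Sets was not tested against that between kits. The lists held 2782 to 6641 peaks in Set 1, 5475 to 8844 in Set 2 and 15032 to 18316 in Set 3. In Set 1 KAPA had the longest list and NEB the shortest, in Set 2 Bioo had the longest and KAPA the shortest, and in Set 3 Diagenode had the longest and NEB the shortest. The geometric mean was 6221 peaks in NEB, 8394 in Bioo, 8519 in KAPA and 9432 in Diagenode, with SDs on the log2 scale of 1.22, 1.04, 0.87 and 0.91 (n = 3 each), and the test of kits did not pass (exact permutation p = 0.881). The tests of covered length and median width did not pass either (exact permutation p = 0.937 and 0.376), although the median width was larger in Bioo and NEB than in Diagenode and KAPA in each of the 3 Sets. Recovery of the 4391 CTCF reference regions averaged 63.9 ± 30.9% in Bioo, 69.0 ± 28.3% in NEB, 74.7 ± 27.3% in KAPA and 81.7 ± 17.9% in Diagenode (exact permutation p = 0.838, n = 3). These CTCF tests did not use the Set as a block, so the spread between Sets counted as noise and limits what they can detect.

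**Figure D3:**
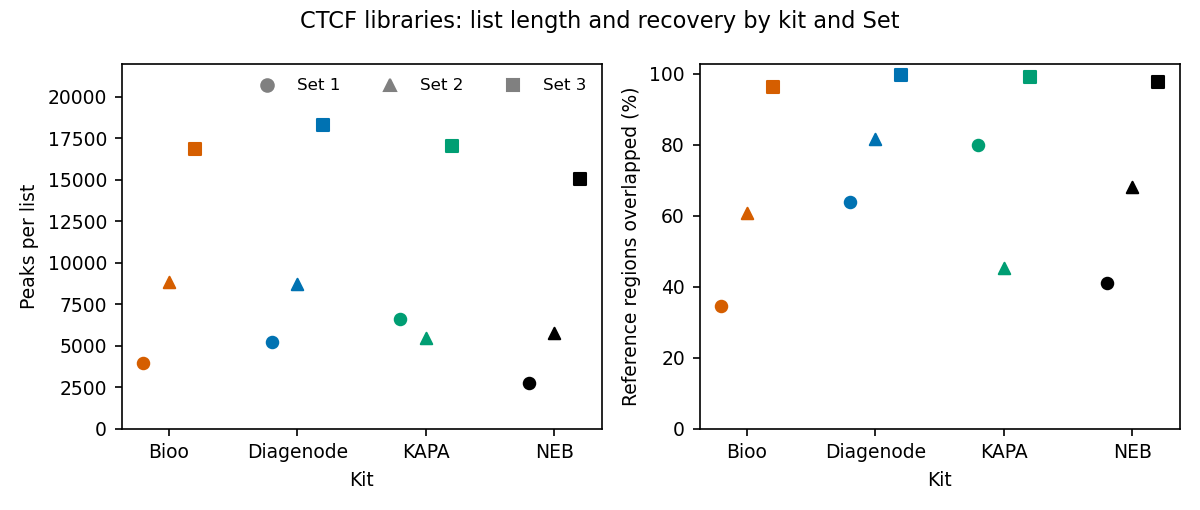
CTCF peaks per list (left) and percent of CTCF reference regions overlapped (right) for each kit, with 1 point per library, circles for Set 1, triangles for Set 2 and squares for Set 3. Every kit has its longest list in Set 3, between 15032 and 18316 peaks.

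The title of the series names a dependence of kit performance on the class of target, which was tested on list length between the histone marks. The Bioo deficit was larger for H3K27me3: the log2 Bioo to NEB ratio was lower in H3K27me3 than in H3K4me3 by 0.41 on average, in 6 of 6 inputs. The direction turned after adjustment for the stated read number, to -0.62 with 0 of 6 inputs positive (exact p = 0.03125), and on covered length, a test added after the result was seen, the value was 0.31 with 3 of 6 inputs positive (exact p = 0.875). The exact sign-flip p was 0.03125, the smallest that 6 inputs allow, and the p adjusted over the 6 kit pairs was 0.0625. The difference did not pass after adjustment, but a pair alone at that smallest p could not have passed it, so the adjustment cannot decide. Against Diagenode the Bioo deficit was larger in H3K27me3 by 0.38, with the same p-values by exact sign-flip, but this value was 0.035 without Set 1 (exact p = 0.594) and 0.72 without Set 2 (exact p = 0.03125). The Bioo to NEB value was 0.25 without Set 1 and 0.80 at the stricter threshold (exact p = 0.03125 for both). Without the 100 pg libraries the Bioo to NEB value was 0.18, and 0.28 when adjusted for the stated read number, so the turn in direction rested on 100 pg (exact p = 0.0625 for both, the smallest that 5 inputs allow).

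At single positions, 620 of the 10005 H3K4me3 regions tested were called more or less often in one kit than in the others. The region test compared kits at the same input and was not adjusted for the stated read number. Bioo libraries called 562 of them less often and 5 more often, while Diagenode called 39, NEB 18 and KAPA 4 more often, where a region can count for more than 1 kit. The rule for named regions gave, for Bioo, chromosome 2 from 91936604 to 91937545, chromosome 22 from 43738345 to 43740040 and chromosome 4 from 7193711 to 7195265, each called in 0 of 12 Bioo libraries and 36 of 36 others (adjusted p = 1.4e-05, exact conditional test). Bioo libraries more often called chromosome 22 from 46374308 to 46375511 (8 of 12 against 0 of 36), chromosome 5 from 92915248 to 92918102 (9 of 12 against 5 of 36) and chromosome 5 from 58592614 to 58593407 (5 of 12 against 0 of 36).

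For the other kits the H3K4me3 regions were called more often. Diagenode called chromosome 21 from 32460122 to 32461251 in 12 of 12 libraries against 8 of 36, chromosome 8 from 751747 to 752512 in 8 of 12 against 1 of 36, and chromosome 11 from 64993000 to 64993868 in 10 of 12 against 5 of 36. KAPA called chromosome 17 from 77786748 to 77787895 in 9 of 12 against 3 of 36, chromosome 6 from 1316508 to 1317519 in 7 of 12 against 1 of 36, and chromosome 6 from 33284629 to 33286741 in 11 of 12 against 13 of 36. NEB called chromosome 12 from 132662934 to 132664205 in 7 of 12 against 1 of 36, chromosome 19 from 4580546 to 4582218 in 9 of 12 against 4 of 36, and chromosome 17 from 55434035 to 55435097 in 7 of 12 against 1 of 36. Their adjusted p-values ran from 0.00155 to 0.0217 (exact conditional test). At inputs of 1, 5 and 10 ng alone 23 regions passed, all called less often in Bioo. Without the libraries under 5 M reads 274 passed, and with either Set alone 0 passed, where 6 libraries per kit allow no p below 0.000244.

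For H3K27me3, 105 of the 3911 domains tested were called more or less often in one kit than in the others. The test of these domains was not adjusted for the stated read number either, so kit and read number cannot be told apart. Bioo called 53 less often, and Diagenode called 54 more often and 1 less often. Bioo libraries did not call chromosome 16 from 600001 to 640000 (0 of 12 against 30 of 36) or chromosome 1 from 6440001 to 6580000 (0 of 12 against 29 of 36), and seldom called chromosome 1 from 31640001 to 31720000 (2 of 12 against 33 of 36). Diagenode libraries more often called chromosome 11 from 47360001 to 47440000 (10 of 12 against 1 of 36), chromosome 2 from 121060001 to 121160000 (9 of 12 against 1 of 36) and chromosome 12 from 125060001 to 125160000 (8 of 12 against 0 of 36). The domain that Diagenode called less often spanned chromosome 2 from 140780001 to 141780000 (3 of 12 against 30 of 36, adjusted p = 0.0118, exact conditional test). At inputs of 1, 5 and 10 ng alone 0 domains passed, with 329 at an unadjusted p under 0.05 where 10324 tests were made over domains and kits. Without the libraries under 5 M reads 52 passed.

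No CTCF region passed: 0 of 19340 tested by the exact conditional test, with 706 at an unadjusted p under 0.05. Over regions and kits there were 77360 tests, so many low p-values would arise without any kit effect. The smallest p of any region was 0.00455, and in simulated data of this layout the test recovered 0% of changed regions, so kit-dependent CTCF sites were not detectable with 3 libraries per kit.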

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

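In 3 kit pairs a difference in the effect on list length between H3K4me3 and H3K27me3 passed an exact sign-flip test over inputs before adjustment but not after it (p = 0.03125 each, adjusted p = 0.0625). That p is the smallest that 6 inputs allow, and with only 3 of the 6 pairs at it none could pass, so the adjustment cannot decide. The log2 difference was 0.41 for Bioo against NEB, 0.38 for Bioo against Diagenode and 0.17 for Bioo against KAPA, in the same direction at 6 of 6 inputs. The Bioo to KAPA value did not hold: it was -0.31 without Set 1 (3 of 6 inputs, exact p = 0.719) and 0.077 at the stricter threshold (5 of 6 inputs, exact p = 0.531). The tests below on covered length, on lists without 100 pg, and on Set 1 against Set 2 were chosen after the result was seen.

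The Bioo to NEB difference between the marks was weighed against the stated read number and against the counting of domains. With list length adjusted for stated reads, at the slope within kit and input, the difference turned to -0.62 (0 of 6 inputs positive, exact sign-flip p = 0.03125), and by the rule set beforehand this made the read number the cause. That verdict was changed to undecided after the result was seen, because the H3K27me3 slope was 1.04 with the 100 pg libraries and 0.088 without them. Without 100 pg the adjusted difference was 0.28, in 5 of 5 inputs, against 0.18 before adjustment (exact p = 0.0625 for both, the smallest that 5 inputs allow). On covered length the difference was 0.31 and positive at only 3 of 6 inputs (exact p = 0.875), so both technical explanations and a difference between promoter peaks and broad domains stay open.

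The 562 H3K4me3 regions called less often in Bioo were weighed next. Of 100 splits of the libraries within input, the real one included, 1 gave as many regions with kit-dependent calling as the 620 observed, and the highest other gave 0. That is the smallest share that 100 splits can give. The splits treat all libraries of an input as exchangeable. They therefore cannot tell a kit effect from a dependence between the libraries of one kit and Set. In the 10 ng libraries the regions were called in 55.1% of cases in Bioo and 92.3% in the other kits, between the limits set beforehand, so a part of the loss may follow the low stated read numbers of the small inputs. The 562 regions were chosen over all inputs, these 10 ng libraries included, so the choice itself widens that gap. Read number as the whole cause is argued against by 510 regions chosen on inputs of 100 pg to 1 ng alone: the 4 Bioo libraries of 5 and 10 ng, with 27 to 33 M stated reads, called 61.1 ± 6.56% of them, at most 67.3%, while the 12 other libraries, with 16 to 33 M, called at least 80.6%. An uneven loss was predicted to make the recovery on gene-dense chromosomes (16, 17, 19, 20 and 22) minus that on gene-poor ones (4, 13 and 18) lowest in Bioo, but it was highest there, 2.77 percentage points against a mean of 1.16 (permutation p = 0.020), which is undecided since a kit that misses more has more room for a difference.

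Set 1 H3K4me3 lists were longer than Set 2 lists by 1.16-fold in NEB and 1.1-fold in Bioo, at 6 of 6 inputs each, and by 1.01-fold in Diagenode, also at 6 of 6 (exact sign-flip p = 0.03125, adjusted p = 0.0417 for each), against 0.981-fold in KAPA. The stated read number as the whole cause is argued against by the 2 Bioo or NEB pairs of lists with no more stated reads in Set 1, since in 2 of 2 the Set 1 list was longer, but both ratios, 1.09, were the lowest of their kit, and those of the other NEB pairs ran from 1.14 to 1.2, so read number as a part of the cause stays open. Of the 3074 regions that NEB called at 10 ng in Set 1 and not in Set 2, 39% were also called by Bioo in Set 1 and not in Set 2, against 10.7% in Diagenode and 11.1% in KAPA. At 10 ng, however, Bioo had 16857 peaks in Set 1 and 15533 in Set 2. Diagenode had 15894 and 15753, and KAPA 15388 and 15071. The higher share in Bioo may follow in part from its larger surplus in Set 1. A hypothesis that fits is that the Bioo and NEB libraries of one Set shared a source, such as one immunoprecipitation, that the other kits did not, which the labels do not record.

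For the 105 H3K27me3 domains with kit-dependent calling, 1 of 100 splits gave as many and the highest other gave 0, with the same limits of the splits as for H3K4me3. For CTCF the real count and the highest other were both 0, so 100 of 100 splits gave as many, and no split of this design can decide.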

How the results depend on the processing

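Of the alternative values, 125 kept their direction and side of the threshold (counts: stayed within 1.5 times), 16 fell short of the threshold, 15 newly passed it, 14 turned direction and 10 counts moved. The alternatives without the libraries under 5 M reads and in 20 kb bins were chosen after seeing the data. Except where stated, the cause was not tested. The planned promoter and GC content tests were not run, and merging within 1000 bp cannot change domains on a 20 kb grid. Stated read number and kit cannot be separated at 100 pg.

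For H3K4me3, the NEB to Bioo ratio of list lengths was 1.21 at the stricter threshold, 1.05 to 1.11 leaving out each Set, 0.998 at 1, 5 and 10 ng and 0.989 adjusted for stated reads, while that of covered length was 1.12 without libraries under 5 M reads. For H3K27me3 the ratio of list lengths adjusted for stated reads was 0.925, and that of covered length without libraries under 5 M reads 1.08. The CTCF Bioo to NEB ratio of covered length was 0.953 with the same number of top-ranked peaks.

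Without 100 pg the log2 slope per doubling was -0.0026 in KAPA for H3K4me3, and 0.033 in Bioo, 0.017 in Diagenode and -0.0028 in KAPA for H3K27me3, and the H3K4me3 difference in slope was 0.037. At the stricter threshold the NEB slopes were 0.00022 for H3K4me3 and 0.0082 for H3K27me3. Leaving out each Set, slopes ran from -0.0073 to 0.0010 in NEB and 0.00094 to 0.033 in KAPA for H3K4me3, and for H3K27me3 from 0.073 to 0.31 in Bioo, 0.038 to 0.063 in Diagenode, 0.048 to 0.21 in KAPA and -0.015 to 0.0032 in NEB.

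Leaving out each Set, the NEB to Bioo difference in H3K27me3 recovery was 11.8 to 18.2 percentage points. The NEB to Bioo difference in H3K27me3 overlap between Sets was 6.13 as a share of peaks and 1.88 at 1, 5 and 10 ng, and same-kit overlap exceeded other-kit overlap by 1.42 for H3K27me3 as a share of peaks and by 0.86 for CTCF with the same number of top-ranked peaks. The difference between marks was 0.18 for Bioo against NEB and -0.010 for Diagenode against NEB without 100 pg. Leaving out each Set it was 0.035 to 0.72 for Bioo against Diagenode, -0.31 to 0.65 for Bioo against KAPA, -0.15 to 0.22 for Diagenode against NEB and -0.089 to 0.56 for KAPA against NEB.

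Kit-dependent H3K4me3 regions numbered 1109 at the stricter threshold, 23 at 1, 5 and 10 ng, 274 without libraries under 5 M reads and 0 without either Set (1501 and 2686 at an unadjusted p under 0.05). For H3K27me3 they numbered 0 at 1, 5 and 10 ng (329 unadjusted), 52 without libraries under 5 M reads, 404 as 20 kb bins and 0 without either Set (815 and 507 unadjusted). With 1 Set no p can fall below 0.000244, which follows from fewer libraries. The unadjusted counts stand against 22516 and 32684 tests over regions and kits for H3K4me3. For H3K27me3 the tests numbered 10324 at 1, 5 and 10 ng, and 13212 and 11808 without either Set.

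Set numbers did not meet the rule for pairing. Deviations of libraries with the same Set number were correlated for each kit pair, at each input or, for CTCF, in each Set. The correlation was over 0.1 in 5 of 36 cases for H3K4me3, 32 of 36 for H3K27me3 and 10 of 18 for CTCF. Of the libraries, 42 of 48, 44 of 48 and 9 of 12 correlated best with their own number. For the histone marks, the deviations of a kit's Sets at the same input mirror each other, so both libraries always share the same outcome. The histone library counts therefore do not hold independent outcomes, and without pairing each outcome would be as likely as not. Between Bioo and NEB the correlation ran from 0.118 to 0.377 for H3K4me3 and from 0.173 to 0.466 for H3K27me3 at 250 pg and above, but was 0.00036 and -0.0039 at 100 pg. With the Set number as a block, kit-dependent regions numbered 588 for H3K4me3 and 91 for H3K27me3. The block values were 1.08 for H3K4me3 list length (permutation p = 0.0380), 1.21 for CTCF width (exact p = 0.0104, Bioo and NEB wider than Diagenode and KAPA in each of 3 Sets) and 0.13 for the KAPA H3K27me3 slope (permutation p = 0.0622). For the difference between marks the block gave 12 values per kit pair, of which 12 of 12 were positive for Bioo against NEB (0.41, exact p = 0.000488, adjusted p = 0.00293) and 11 of 12 for Bioo against Diagenode (0.38, adjusted p = 0.0225 by the exact test), so both passed, as did Diagenode against KAPA (-0.21, exact p = 0.00635, adjusted p = 0.019), while for Bioo against KAPA 9 of 12 were positive (0.17, exact p = 0.505).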

Other observations

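H3K4me3 and H3K27me3 lay mostly apart. Of the 13721 autosomal H3K4me3 reference regions, 2662 (19.4%) had their midpoint in an H3K27me3 reference domain, against 36.2% to 42.7% over 1000 random shifts of the regions along their chromosome (1-sided circular-shift permutation p = 0.000999, the smallest that the shifts can give). CTCF reference sites overlapped H3K4me3 regions more often than after shifting: 28.4% of 4371 did so, against 1.17% to 2.75% (permutation p = 0.000999). They were also more frequent at the edges of H3K27me3 domains, with 15.2% within 20 kb of a domain end against 5.42% to 8.01% after shifting, and 14.7% against 5.30% to 8.31% for the 3130 sites that overlapped no H3K4me3 region (permutation p = 0.000999 for both). Inside domains the share of CTCF sites, 37.7%, lay within the shifted range of 34.9% to 44.0%. Shifts ignore gene density and assembly gaps, which may account for part of these differences, and the tests were chosen after the main results were seen, before these values were.

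Chromosome 19 had the densest H3K4me3 reference, 17.4 regions per Mb, and chromosome 13 the sparsest, 2.09 per Mb. H3K27me3 reference domains covered 50.4% of chromosome 18 and 25% of chromosome 22, as shares of the length up to the last listed region. That length, also used for the densities, includes assembly gaps, where no region can be called. Values of chromosomes with large gaps are therefore lowered. The longest H3K27me3 reference domain, 7700 kb, ran on chromosome 4 from 29880001 to 37580000, and the widest H3K4me3 reference region, 12.4 kb, on chromosome 17 from 46795245 to 46807675.

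The choices here of the chromosome groups and of the list shares were made after the main results, and the comparison without libraries under 5 M reads after its own result was seen. Diagenode H3K27me3 libraries recovered 97.6% of reference domains on gene-dense chromosomes (16, 17, 19, 20 and 22) and 91.6% on gene-poor ones (4, 13 and 18). The difference of 6.03 ± 4.53 percentage points (SD, n = 12) stood against 1.92 in Bioo, 1.82 in KAPA and 1.36 in NEB (permutation p = 0.00177 over kits). A hypothesis is that Diagenode lists are shifted toward gene-dense chromosomes. The share of covered length on the gene-dense ones, of that on both groups, was 53% in Diagenode, 50.2% in Bioo, 49.7% in KAPA and 46.3% in NEB, and the test of kits did not pass (permutation p = 0.0926, adjusted p = 0.139 over 3 targets). Without the libraries under 5 M reads it was 53% in Diagenode against 45.3% to 46.3% in the other kits (permutation p = 0.00245). That filter removed the Bioo and KAPA libraries of 100 pg, at 64.9% to 78.6%, and kept those of Diagenode, at 54.2% and 65.3%. The Diagenode excess also lay more in Set 2. At 10 ng Diagenode had 40.8% in Set 1, against 38.6% to 42.3% in the other kits, and 54.5% in Set 2, against 44.4% to 48.7%. At 250 pg it had 50.6% against 44.5% to 48.6%, and 60.1% against 46.7% to 52.9%. The question stays open, and base composition was not measured.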
